A study of Mus musculus with 8 samples.

How the data were processed

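RNA from mouse footpads, taken as punch biopsies, was measured on 8 two-colour Agilent arrays, 4 from wild-type mice and 4 from mice with a conditional knockout (cKO) of Foxc1, a forkhead transcription factor. Per the labels, Cy3 carried the footpad RNA and Cy5 a universal mouse reference RNA on every array, with no dye swap, so a dye effect common to all arrays cancels in the difference between groups. The arrays lay on 2 slides. Slide 1 held replicates 1 and 2 of each group and slide 2 held replicates 3 and 4. Wild-type samples were at positions 1 and 2 and cKO samples at positions 3 and 4 of both slides, so position and genotype cannot be told apart in Cy3. The labels number the replicates 1 to 4 but also call them replicates out of 2, and the mouse identifiers repeat only slide and position. P-values therefore measure the spread between these samples, which may in part be technical.

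The spot intensities were written by Agilent Feature Extraction 9.5.1.1, per the file headers, and are linear mean signals and local background signals of both channels. The deposited value table is on a log10 scale. Set against the scanner files, each of its values equalled log10 of the processed Cy3 signal minus log10 of the processed Cy5 signal plus the mean log10 Cy5 signal over the 8 arrays, within 2e-04. Its column medians ranged from 2.395 to 2.406. Higher values in it mean more Cy3, and no part of its scale, centring or direction stayed unknown.

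The background was corrected with normexp at an offset of 50, and log2 ratios of Cy3 over Cy5 were normalized within each array by loess, with control spots at weight 0. No normalization between arrays followed. Control spots and spots marked as outliers were left out and spots of one probe were averaged. A probe was tested if it was well above background in Cy3 on at least 4 of the 8 arrays, whatever their group, and had at least 2 values per group. Of 42006 probes, 29880 met the first condition and 29879 were tested. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05. The Cy5 channel alone, after normexp and quantile normalization, was tested the same way as a negative control. Single measures of the arrays were compared with two-sided exact permutation tests, for which 4 arrays against 4 can give no p below 0.0286. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for probe sequences and plots.

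The fit was tested on simulated data with 29766 probes, of which 200 were changed. It called 71.64% of the probes changed 1.5-fold, 94.03% of those changed 2-fold and 96.97% of those changed 4-fold, with 8 false calls. The simulated noise was normal and independent between arrays, with the same SD per probe in both groups and no slide or position effect. The real data differ from this, so these shares and false calls need not hold for them. The number of arrays, 4 per group, limits the precision.

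The files used here do not pair probes with genes. Each probe has an identifier and a sequence of 60 bases, and 0 of the 42006 identifiers matched the 49997 genes of the reference table (GRCm38.p6). The planned tests of Foxc1 itself, of gene lists (with camera or fry), including lists for other cell types and sex-linked genes, and of the mean over the probes of a gene were therefore not run, and what was planned per gene was tested per probe. The probes described were set by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among probes past the threshold whose 4 cKO values all lay on one side of the 4 wild-type values.

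Alternatives fixed before the data were examined changed the background correction, the normalization, the source of the values, the filter on dim probes, the variance model, the slide or replicate number as a block, and the arrays used. Processed signals and the deposited table replaced background correction and normalization together, and Cy3 alone changed channel and normalization together. The others changed one choice at a time. Leaving out single arrays in the Cy5 test was added after seeing the data.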

Results

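Footpads, the hairless skin of the mouse paw that carries its sweat glands, were compared between wild-type mice and mice with a conditional knockout of Foxc1. The series title names absent sweating in mice lacking Foxc1, and the comparison asks which transcripts differ between the footpads of both genotypes. There were 4 arrays per group. Foxc1 itself was not analysed here, since the files used here do not pair probes with genes, and probes are given by identifier and sequence. Between 66.05% and 68.34% of the 42006 probes were well above background in Cy3 on the wild-type arrays and between 71.38% and 76.22% on the cKO arrays. Correlations of log2 ratios across probes, which are not independent replicates, ranged from 0.9749 to 0.9927 between arrays of one group and from 0.9634 to 0.9842 between arrays of different groups. No pair of arrays held the same values throughout.

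In cKO footpads 677 probes were higher and 270 were lower than in wild type (limma, Benjamini-Hochberg FDR of 0.05), which together are 947 of 29879 tested, or 3.17%. Cy3 alone gave 247 higher and 109 lower, lower probes numbered 171 with processed signals, 172 with the deposited table and 150 with median centring, and leaving out any 1 array gave 301 to 575 higher and 112 (without wild-type replicate 1) to 179 lower. Of the 947 probes, 289 rose and 59 fell at least 1.5-fold, 97 rose and 19 fell at least 2-fold, 19 rose and 6 fell at least 4-fold, and 12 rose and 1 fell at least 8-fold. With processed signals or the deposited table, at least 2-fold changes numbered 178 rises and 28 falls, at least 4-fold changes 57 rises and 12 falls, and at least 8-fold changes 21 rises and 6 falls. At least 1.5-fold rises numbered 175 in Cy3 alone and 190 without wild-type replicate 3. The median size of the change was 0.54 on the log2 scale among the risers and 0.41 among the fallers. The median change over all tested probes was -0.0047 on the log2 scale.

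**Figure D1:**
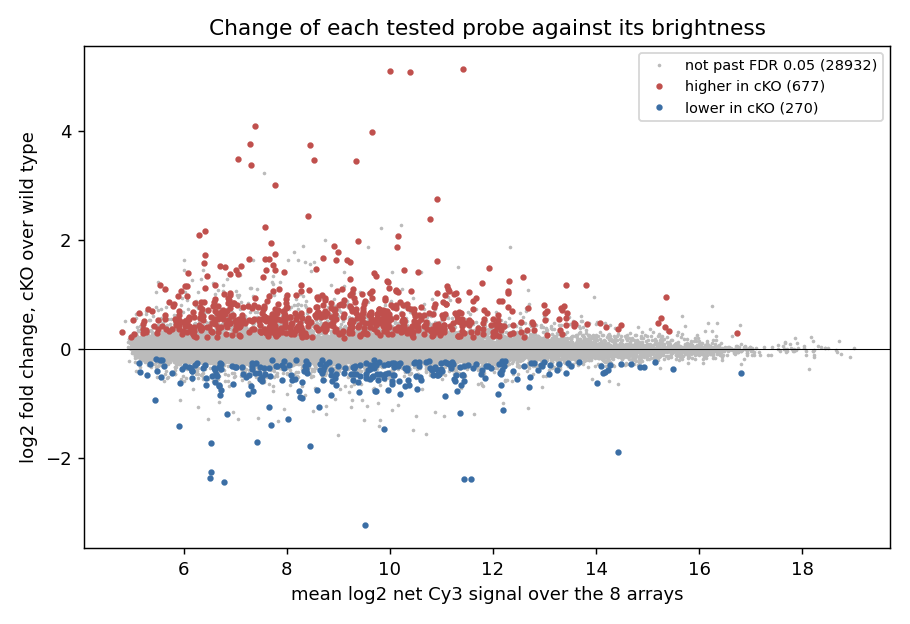
Log2 fold change of cKO over wild type (vertical axis) against the mean log2 net Cy3 signal over the 8 arrays (horizontal axis), 1 point per tested probe. The 677 higher and 270 lower probes are coloured, and the largest rises reach further from 0 than the largest falls.

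Under the settings used, the largest fitted rise was at probe Z00058188-1 (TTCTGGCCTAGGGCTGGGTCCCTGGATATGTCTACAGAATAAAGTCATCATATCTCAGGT). Its log2 ratio to the reference was -0.94 ± 0.50 (SD, n = 4) in wild type and 4.198 ± 1.643 (SD, n = 4) in cKO, a limma log2 fold change of 5.13 ± 0.71 (SE) with an adjusted p of 0.00889. Probe Z00023637-1 (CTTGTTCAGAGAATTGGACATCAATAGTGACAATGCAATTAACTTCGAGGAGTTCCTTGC) rose by 5.09 ± 0.73 (SE) on the same scale, from -0.55 ± 0.38 to 4.54 ± 1.73 (SD, n = 4 each), with a limma adjusted p of 0.0106. Without cKO replicate 1 these log2 fold changes were 5.82 and 5.77, and without cKO replicate 2 the latter was 4.49. The 12 largest fitted rises spanned 8.04-fold to 35.1-fold, with limma adjusted p from 6.59e-07 to 0.0287. For 3 of these 12, ranked 4, 6 and 8, no wild-type array was well above background, so their fitted folds rest on wild-type signal near background. The riser ranked 11 was well above background in Cy3 on 1 of the 4 wild-type arrays. In Cy5, the risers ranked 3, 4, 6, 7, 8 and 11 were not well above background on at least 1 array. Their ratios rest in part on reference signal near background. The order of the 12 depended on the processing, and the largest fitted log2 fold change was 6.25 at the riser ranked 4 with processed signals or the deposited table, and 7.72 at the riser ranked 3 in Cy3 alone.

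Under the settings used, the largest fitted fall was at probe Z00022421-1 (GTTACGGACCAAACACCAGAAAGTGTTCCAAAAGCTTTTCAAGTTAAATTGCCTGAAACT). Its log2 ratio was 0.13 ± 0.16 in wild type and -3.10 ± 0.16 in cKO (SD, n = 4 each), a limma log2 fold change of -3.23 ± 0.10 (SE) with an adjusted p of 2.56e-06. Probe Z00072088-1 (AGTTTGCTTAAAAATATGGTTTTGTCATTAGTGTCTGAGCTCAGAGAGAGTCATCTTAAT) went from 2.15 ± 0.38 to -0.28 ± 0.09 (SD, n = 4 each), a limma log2 fold change of -2.44 ± 0.17 (SE) with an adjusted p of 0.00028, and was well above background on 3 of the 4 cKO arrays. With processed signals or the deposited table its log2 fold change was -4.19, and the fallers ranked 5 and 6, at -4.81 and -4.02, also went further than Z00022421-1, at -3.50. The 12 largest fitted falls spanned 2.67-fold to 9.41-fold, with limma adjusted p from 2.56e-06 to 0.0119. The fallers ranked 5, 6 and 12 were well above background in Cy3 on 1, 3 and 2 of the 4 cKO arrays. In Cy5, the fallers ranked 5, 9 and 12 were not well above background on at least 1 array.

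Among the 12 risers the median SD was 1.17 over the cKO arrays and 0.14 over the wild-type arrays, and it was larger in cKO for 11 of 12. Of these risers, ranks 4, 6 and 8 were well above background on 0 wild-type arrays and rank 11 on 1. The offset may narrow the spread of such dim signal. Among the 12 fallers the median SD was 0.118 in cKO and 0.292 in wild type, and it was larger in cKO for 0 of 12, of which ranks 2, 5, 6 and 12 were not well above background on every cKO array. Over all 677 risers the SD was larger in cKO for 65.3%, over all 270 fallers for 47.8% and over the probes not past the threshold for 50.2%. Replicate 2 was the highest cKO array for 11 of the 12 risers and replicate 1 the lowest for 10. The cKO replicates 2 and 4 lay at position 4 of their slides and replicates 1 and 3 at position 3. The riser values in cKO spanned from 0.38 to 3.85 log2 units between the lowest and highest array, against 0.12 to 0.51 for the fallers.

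**Figure D2:**
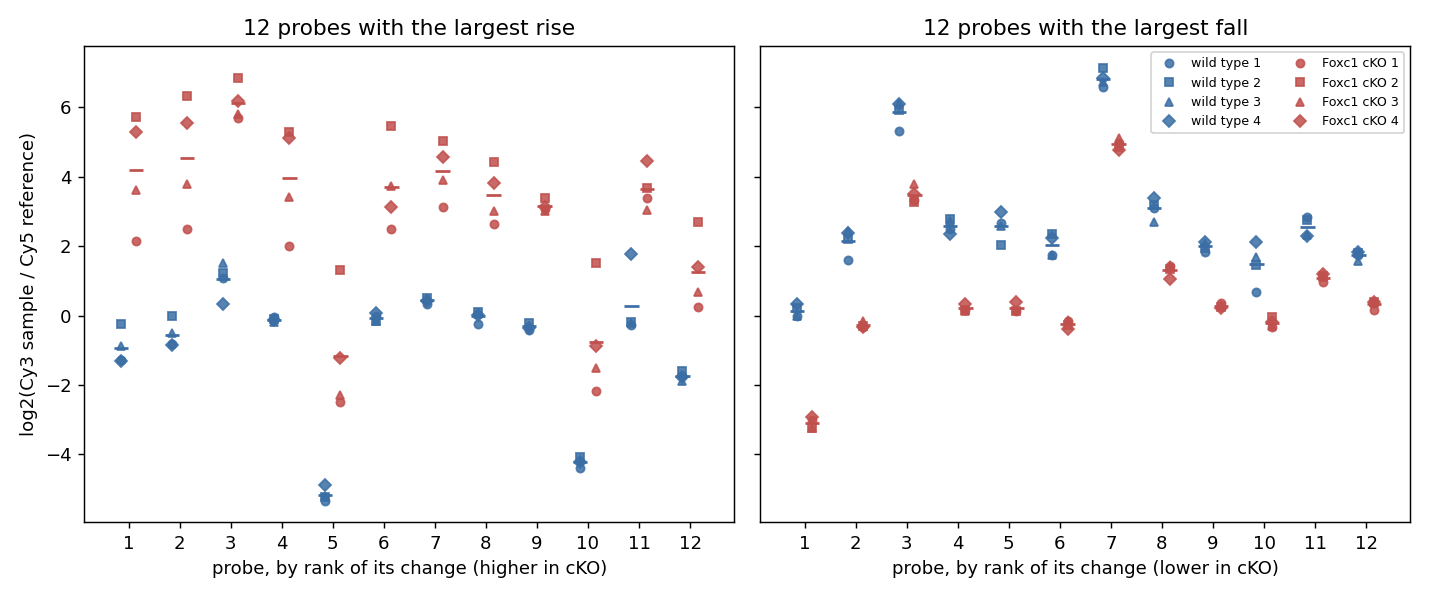
Log2 ratio of Cy3 sample to Cy5 reference (vertical axis) of the 12 probes with the largest rise and the 12 with the largest fall, by rank (horizontal axis); each point is 1 array, marked by replicate, and short lines are group means. Points of the 4 cKO arrays span up to 3.85 log2 units for the risers and up to 0.51 for the fallers.

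Within slide 1, with 2 arrays per group, limma called 147 probes higher and 73 lower. Of these 220 probes, 202 (91.8%) changed in the same direction on slide 2, against 60.8% of all probes, 124 of them with an unadjusted limma p under 0.05, and 135 were among the 947. The median ratio of the slide 2 change to the slide 1 change was 0.646. The probes were chosen by their slide 1 change, so a ratio under 1 was likely in advance. It does not show a weaker effect on slide 2. Within slide 2 alone, 3 probes were higher and 5 lower. With slide as a block the count was 1008, 717 higher and 291 lower. The count fell by over 1.5 times without wild-type replicate 1 (413), 2 (507), 3 (430) or 4 (580) and without cKO replicate 2 (506) or 4 (594). The risers ranked 5 and 10 were not past the threshold when any 1 wild-type array or cKO replicate 4 was left out, with limma adjusted p from 0.0536 to 0.0868, while their log2 fold changes were 3.92 to 4.07 (3.98 with all arrays) and 3.40 to 3.49 (3.45 with all arrays). Without cKO replicate 2 both stayed past the threshold, but their log2 fold changes dropped to 3.155 and 2.698.

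**Figure D3:**
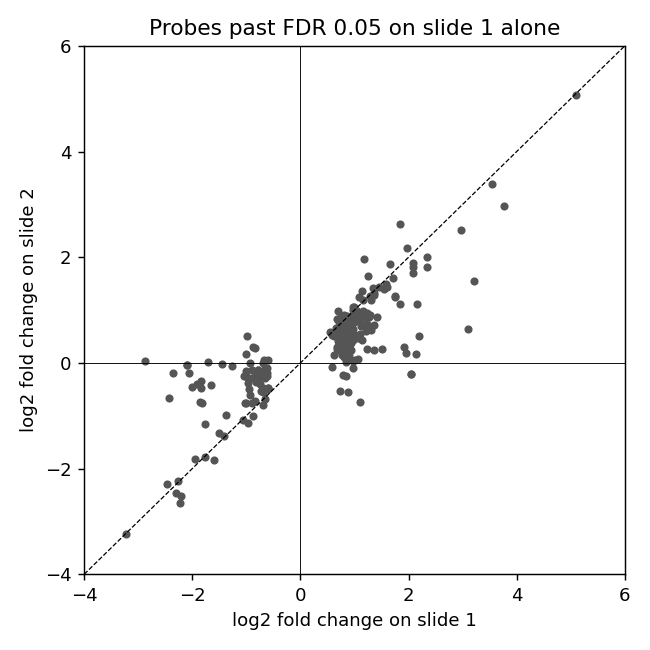
Log2 fold change of cKO over wild type on slide 2 (vertical axis) against slide 1 (horizontal axis) for the 220 probes past the threshold on slide 1 alone, 1 point per probe, with the line of equal change dashed. Of the 220, 202 lie on the same side of 0 on both slides.

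The reference RNA in Cy5, which was the same on every array, gave 0 of 32693 probes past the threshold between the same groups of arrays in limma, with 534 at an unadjusted p under 0.05 (1.63%). With slide as a block it gave 0, with 1425 at an unadjusted p under 0.05 (4.36%).

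The share of probes well above background in Cy3 was 67.2% ± 1.16 in wild type and 73.8% ± 1.98 in cKO (SD, n = 4 each), a difference of 6.66 percentage points (exact permutation p = 0.0286, the smallest possible; 0.0857 adjusted over 9 array measures). On slide 1 the shares were 66.05% and 66.27% in wild type and 73.97% and 73.71% in cKO, and on slide 2 they were 67.96% and 68.34% against 76.22% and 71.38%. In Cy5 the shares were 76.7% ± 2.60 and 78.8% ± 3.51 (exact permutation p = 0.4, n = 4 each, 0.514 adjusted). The median net Cy3 signal was 102.3 ± 3.73 in wild type and 107.0 ± 5.11 in cKO (exact permutation p = 0.257, n = 4 each, 0.386 adjusted).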

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

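The split counts of the main comparison, within slides too, the test of position from the Cy5 count, the comparison of spread over probes not past the threshold and the comparison of median signals were chosen only after their results were seen, and the measures from the file headers were added then too.

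Dixon's ratio marked 6 of 62 groups of 4 arrays, and chance marks about 1 in 20. The riser ranked 11 was far higher on wild-type replicate 4 (1.78) than on the other wild-type arrays (-0.26 to -0.19), with a ratio of 0.969. Among the fallers, rank 4 was high on cKO replicate 4 (0.839), rank 5 was high on cKO replicate 4 (0.869) and rank 12 was low on cKO replicate 1 (0.872). The share of probes well above background in Cy5 was high on cKO replicate 3 (84.0%, ratio 0.865). The additive error of Cy3 in the file headers was high on cKO replicate 4 (8.86, ratio 0.982).

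The first pattern is the count of 947 probes. Whether chance can be excluded depends on treating arrays of both slides as interchangeable: of all 35 splits of the 8 arrays, which ignore slide, 1, the real one, gave as many, and the highest other, the split by slide, gave 125. Splits that keep 2 arrays of each slide on each side number 18, too few for a share under 0.05; with slide as a block, 1 of them, the real one, gave 1008 and the highest other gave 5. With the limit of 1.5-fold and slide ignored, the real split gave 348, 1 of 35, and the highest other gave 39. Position acting on both channels would move the one RNA in Cy5, which gave 0 probes where Cy3 alone gave 356. An effect equal in both channels would cancel in the ratios behind the 947. For such an effect the Cy5 count therefore adds nothing about the 947. Slide differences widen the spread in that Cy5 test, but with slide as a block it also gave 0, with 4.36% at an unadjusted limma p under 0.05. Cy3 alone was not tested with slide as a block. A Cy3 background that differed between the groups' arrays would leave few calls among bright probes, yet 22.2% of the 947 lay in the brightest 25% of tested probes. Brightness was averaged over all 8 arrays, so a rise itself makes a probe brighter. For the 11.2% and 31.5% of calls in the dimmest 2 of the 4 brightness groups, background is not excluded. An effect of position on Cy3 alone cannot be told apart from genotype, and a difference between the genotypes stays open as well.

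In Cy5 the real split gave 0, so all 35 splits gave as many, and the split by slide gave 10047. That count points to a structure of the arrays by slide in the Cy5 values. Cy3 alone was not split by slide.

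The second pattern is the larger spread of the risers among cKO arrays. Over the 677 risers the median log2 ratio of the cKO SD to the wild-type SD was 0.327, against -0.066 over the 270 fallers. Noisier cKO arrays would raise it for other probes too, where it was 0.00366, and wild-type signal near background would bring it to 0 among the 629 risers well above background on all 8 arrays, where it was 0.318 (0.21 to 0.385 without 1 cKO array). Compression of dim signal by the offset may contribute: over the 331 risers with bright wild-type signal it was 0.191, but -0.0112 to 0.272 without 1 cKO array, where probes not past the threshold also moved, to between -0.238 and -0.0008. Position stays open too: 74.0% and 78.4% of the risers on slides 1 and 2 were higher at position 4 than at position 3 (44.4% and 48.4% of probes not past the threshold). In size, the median Cy5 difference of the risers was 5.3% of their ratio difference on slide 1 (0.00693 against 0.13). On slide 2 it was 37.0% (0.0608 against 0.164). More Cy5 at position 4 lowers the ratio, so these shares are not parts of the higher ratio. On slide 2 probes not past the threshold shifted by 0.046 in Cy5, while their ratio moved by -0.00586. By the limits set the slides disagree. That this leaves position open was decided after the values were seen, since the reading set at first took 1 slide as enough. An effect of position on Cy3 alone is not tested by these values. Differences between the animals were not tested.

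The third pattern is the larger share of probes well above background in Cy3 on cKO arrays. It is consistent with the detection threshold that the software sets per array: with 1 net signal threshold of 19.0 above the negative controls for all arrays, the difference was 0.383 points in place of 6.66 (0.0819 to 0.678 without 1 array). The negative control spread in the file headers was 10.3 ± 0.945 in wild type and 6.37 ± 0.625 in cKO (exact permutation p = 0.0286, n = 4 each, 0.0857 adjusted). Measures taken from the negative control spots themselves did not separate the groups in this way. Their Cy3 SD was 11.7 ± 12.5 and 3.73 ± 1.32 (exact permutation p = 0.171, n = 4 each, 0.386 adjusted). Their median absolute deviation was 2.846 to 3.387 on wild-type arrays and 2.462 to 3.125 on cKO arrays. Brighter Cy3 on all cKO arrays was not seen, since the lowest cKO median lay below the highest wild-type median (difference -3.98).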

How the results depend on the processing

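Leaving out arrays in the Cy5 test was chosen after seeing the data. The count of 947 (677 higher, 270 lower, 348 at least 1.5-fold) stayed within 1.5 times with no background correction, loess and Aquantile (which leaves ratios as they are and so moved nothing), each filter on dim probes, trend and robust eBayes, and slide as a block. Lower probes numbered 171 with processed signals, 172 with the deposited table and 150 with median centring. Cy3 alone, which changes channel and normalization together, gave 356 (247 higher, 109 lower). Slide 1 alone gave 220 (147 higher, 73 lower, 217 at least 1.5-fold) and slide 2 alone 8 (3 higher, 5 lower, 8 at least 1.5-fold), with fewer arrays. Leaving out 1 array gave 413 to 740 probes, 301 to 575 higher, 112 to 179 lower, 247 to 397 at least 1.5-fold, and 0 to 1 in Cy5 (1 without cKO replicate 3). Rises of at least 4-fold and 8-fold, 19 and 12, were 10 and 6 with the filter on Cy5, and falls of at least 4-fold, 6, were 3 with all 8 arrays in Cy3. The causes of the other shifts were not tested. Of 511 values of the 24 described probes, 471 stayed past the threshold, 40 did not (29 on 1 slide alone) and 0 reversed. Fewer arrays could not reverse probes chosen for separated groups. The riser ranked 6 had a limma adjusted p of 0.113 in Cy3 alone, where its log2 fold change was 4.09 against 3.76. Sizes moved too: 37 of 511 values differed by over 1.5-fold from those reported, for 12 of 24 probes each with processed signals and the deposited table, 3 with Cy3 alone, 1 each with median centring, slide 1 and slide 2, 3 without cKO replicate 1 and 4 without cKO replicate 2. Settings reusing all ratios could move neither size nor sign. The deposited table repeats the changes of the processed signals. The log2 fold change of the riser ranked 3 went from 5.08 to 1.86 with processed signals and 7.72 with Cy3 alone, and that of the faller ranked 12 from -1.42 to -3.14 with processed signals.

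The replicate numbers share no stated origin, and same-numbered arrays deviated together with r across probes of 0.212, 0.188, 0.0891 and 0.421. Same-numbered arrays always shared a slide, so a slide effect may be part of these values. Not every value passed the limit set for pairing, so the arrays were not taken as pairs. Whether the numbers mark pairs stays open. With the replicate block the count was 928 (667 higher, 261 lower, 348 at least 1.5-fold), 695 of them among the 947 (with slide as a block, 850 of 1008), and 7 of 8 arrays correlated best with their own number. Gene lists (estimated correlation, fry) and means over a gene's probes were not run. Signal over background limits 18 called probes not well above background on any wild-type array and 2 on any cKO array.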

Other observations

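Probes that share sequence served as a check within the arrays, chosen after the data were examined. In 1101 pairs of tested probes with at least 20 consecutive bases in common, the log2 changes correlated across pairs with r = 0.825, where pairs are not independent replicates, and 80.4% changed in the same direction. Stretches of 20 bases shared by many probes were left out, so pairs that share only such sequence are missing. Both probes were past the threshold in 32 pairs and changed in the same direction in 31 of them. The pair that differed held the faller ranked 10. In the exception, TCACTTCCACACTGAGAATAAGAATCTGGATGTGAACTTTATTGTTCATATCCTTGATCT fell by 1.71 on the log2 scale (limma adjusted p of 0.0119), while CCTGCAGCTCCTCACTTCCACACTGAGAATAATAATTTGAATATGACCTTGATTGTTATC rose by 0.95 (limma adjusted p of 0.0132). One further pair of probes, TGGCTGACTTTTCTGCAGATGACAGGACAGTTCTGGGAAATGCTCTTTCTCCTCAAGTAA and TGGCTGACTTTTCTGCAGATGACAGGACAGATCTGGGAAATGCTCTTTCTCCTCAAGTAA, rose by 1.60 and 1.63. In 16 pairs only 1 probe was past the threshold, and all 16 changed in the same direction, against 80.4% over all pairs. Of the 1101 pairs, 1053 had neither probe past the threshold. Small changes differ in sign more easily, so higher agreement among pairs with a called probe was likely in advance. Both probes of a pair lie on the same arrays, so this check cannot tell position from genotype.

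The mean GC content of the probes was 45.2% over all tested, 43.2% among the 677 higher and 44.7% among the 270 lower, and GC content and change correlated across probes with r = -0.0443. In a principal component analysis of 29766 probes the first component held 38.7% of the variance. From position 1 to position 4 it was -20.6, -19.6, 6.77 and 27.2 on slide 1 and -18.9, -13.1, 7.70 and 30.4 on slide 2. Positions 1 and 2 held wild type and positions 3 and 4 held cKO. The component separated the groups but also rose at each step of position on both slides, so it cannot tell genotype from position. A slide term was past the threshold in limma for 139 of 29878 probes, with 3663 at an unadjusted p under 0.05, and a difference of the genotype effect between slides for 4, with 1294 at an unadjusted p under 0.05.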
